A study of Mus with 8 samples.

How the data were processed

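Total RNA from 8 cultures of mouse aortic vascular smooth muscle cells was measured on Illumina bead arrays, 1 array per culture, per the labels. 4 cultures came from mice that carried the floxed Tie2 gene without the SM22α Cre transgene and are called WT. 4 came from mice that carried the floxed gene with the transgene and are called KO. The labels name 1 contrast and no covariate. The arrays lay on 2 slides. Slide 1 held the 4 WT arrays and KO replicates 1 and 2, and slide 2 held KO replicates 3 and 4. The labels give replicate numbers but do not say whether each culture came from its own mouse, so the p-values measure only the spread between these cultures.

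The deposited scanner table gives, per the file headers, the mean intensity over the beads of each probe, the SD between the beads, the count of beads and a detection p-value, for 46237 probes on each array. These deposited intensities were not normalized between arrays. The software that made them is not given in the sources used here. The deposited p-values follow, from the values themselves, a one-sided comparison of each bead mean with a single background level per array. A second deposited table, the value table, holds intensities that the authors had normalized between arrays on a linear scale. Its array medians were 114, 114, 115 and 114 in WT replicates 1 to 4 and 114, 116, 113 and 114 in KO replicates 1 to 4. Its rank order within an array was nearly that of the scanner table, so it was neither centred per gene nor turned in sign. The authors' normalization method is not given in the sources used here.

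The probe identifiers in the scanner table did not go with the values beside them. Joined on these identifiers, the intensities of both tables had Spearman correlations between -0.0083 and -0.0047 per array. The rows were therefore matched by their 8 ranks within arrays, which paired 46237 of 46237 rows one to one, with a Spearman correlation of at least 0.9999 per array. The median rank distance to the matched row was 258 and that to the next nearest row was 5258, and in 0 cases was the next row less than 2 times as far. 132 probes of ribosomal protein genes had a median log2 intensity of 12.10 under the value table's identifiers and of 6.79 under the scanner table's own, against 6.85 over all probes. The value table's identifiers were used. Gene names came from the platform annotation given with the data, with symbols updated through the RefSeq gene table of assembly GRCm38.p6. That table was used only for names and for the order of neighbouring genes, since no genome build is named in the sources used here. 35784 probes had 1 gene, 0 had several and 10453 had none listed. 28620 probes were named through the gene identifier, 2637 through an accession, 2128 through the symbol, 2343 through a synonym and 56 kept the symbol of the platform annotation. 3280 symbols were updated.

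The median scanner intensity per array lay between 94.7 and 128.1. The share of probes with a detection p-value under 0.05 lay between 44.9% and 49.5%, and the median probe rested on 38 to 40 beads. The number of arrays limits the precision. Among 937 unannotated probes with the numbering of control probes, 14.4% had a detection p-value under 0.05 on an average array, so a probe called detected here can still be near background.

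Intensities were corrected and normalized with neqc of limma 3.58.1 in R 4.3.3, which fits a normal plus exponential model with the background taken from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. This use of neqc takes detection p-values to come from negative controls. The deposited ones follow a comparison with a single background level per array, so the fitted background is uncertain, above all for dim genes. Probes with a detection p-value under 0.05 on at least 4 of the 8 arrays were kept, 21275 in all, of which 18381 had a gene. Each gene was represented by its kept probe with the highest mean over the 8 arrays, chosen without regard to group, which gave 11859 genes. 4439 of them had several kept probes. Group differences were tested with lmFit and eBayes of limma, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are KO relative to WT on the log2 scale, and a positive value is higher in KO. The 2894 kept probes without a gene were tested apart. For a gene not detected on any array of 1 group, the fold is given as a lower bound. The bound sets the mean of the brighter group against, per array of the dimmer group, the higher of the probe's own value and the lowest value among detected probes.

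42 gene lists were written before the data were examined. 39 had at least 5 tested genes and were tested with camera of limma at a preset correlation between genes of 0.01. The lists of adipocytes and erythroid cells had fewer than 5 tested genes, and the list of sex-linked genes was left out. Camera with an estimated correlation and fry, a rotation test, were run as alternatives. A list score is the mean, over a list's tested genes, of the log2 intensity after each gene's mean over the 8 arrays was subtracted. Differences in scores and in single genes were also tested with an exact permutation test over the 70 assignments of 4 arrays to each group, two-sided, whose smallest possible p is 0.0286.

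The genes to be named were set by a rule written before the data were examined. It took Tek and the tested members of the angiopoietin and Tie list, then in each direction the 10 genes with the largest change among those past the threshold whose groups did not overlap. As 0 genes passed, the 10 with non-overlapping groups and the smallest unadjusted p in each direction were taken and are described as not passing. Up to 4 members with the smallest unadjusted p were taken for each described list, which are the lists with an unadjusted camera p under 0.05. Genes chosen after their values were seen are named as such.

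The alternatives were the authors' value table, normexp with an offset of 50, no background correction, median scaling, cyclic loess, no filter or a stricter filter on dim probes (detection p-value under 0.01 on all 4 arrays of a group), the mean of a gene's probes or every probe on its own, slide as a fixed or random block, slide 1 alone, the replicate number as a block, array quality weights, eBayes with trend and robust settings, adjusted thresholds of 0.1 or of 0.05 with a 1.5-fold minimum, and leaving out each culture in turn. A pair of alternatives was added after seeing the data. They took the unannotated control-like probes as negative controls, and left out WT replicates 1 and 2 together.

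The steps were tested on simulated data with the means of the 11859 genes in the comparison of KO with WT and their spreads as moderated by eBayes. Of 67 genes changed 2-fold, 40.3% were recovered, of 67 changed 4-fold, 88.1%, and of 66 changed 8-fold, 98.5%, while 12 unchanged genes were called, on simulated genes that vary independently of each other. All changed genes were seeded in the same simulated data, which eases the adjusted threshold for each of them. These shares therefore do not give the power where few genes change. Camera gave a contractile list shifted by 0.5 log2 units an adjusted p of 1.6e-14 and called 0 of the other lists, also on independent genes. Joining and plotting used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.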

Results

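Cultured aortic vascular smooth muscle cells of male C57 black 6 mice aged 8 weeks were profiled at passage 1. 4 cultures lacked Cre (WT) and 4 carried Cre under the promoter of SM22α, a smooth muscle gene, which deletes floxed sequence in smooth muscle cells (KO). The floxed gene was Tek, which encodes Tie2, the receptor for angiopoietins best known from endothelial cells. The comparison asks which transcripts differ between cultures with and without the Cre transgene. Median scanner intensity lay between 94.7 and 128.1 over the 8 arrays, and between 44.9% and 49.5% of probes were detected. Pairs of arrays correlated at 0.912 to 0.980 over the 11859 genes tested.

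Tek was lower in each of the 4 KO cultures than in each of the 4 WT cultures. Its log2 intensity was 6.44, 7.42, 6.66 and 6.35 in WT replicates 1 to 4 and 4.78, 5.56, 5.36 and 5.26 in KO replicates 1 to 4. The means were 6.72 ± 0.49 (SD, n = 4) in WT and 5.24 ± 0.33 (SD, n = 4) in KO, a log2 fold change of -1.48 with a standard error of 0.27, or 2.79-fold. The exact permutation test gave p = 0.0286, the smallest it allows. The limma adjusted p was 0.81 over all genes and 0.0061 adjusted over the list alone, the list being the 13 tested angiopoietin and Tie genes. Tek was detected on all 8 arrays through 1 probe, and where that probe lies relative to the deleted part is not given in the sources used here. The log2 fold change was -1.55 both with slide as a block and within slide 1. Here and below these are the same estimate and not separate checks, since slide 2 held KO arrays only. It was -0.61 in the authors' value table, -0.62 without background correction, -0.77 with normexp at an offset of 50 and -0.09 with the unannotated control-like probes as negative controls, an alternative added after seeing the data.

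**Figure D1:**
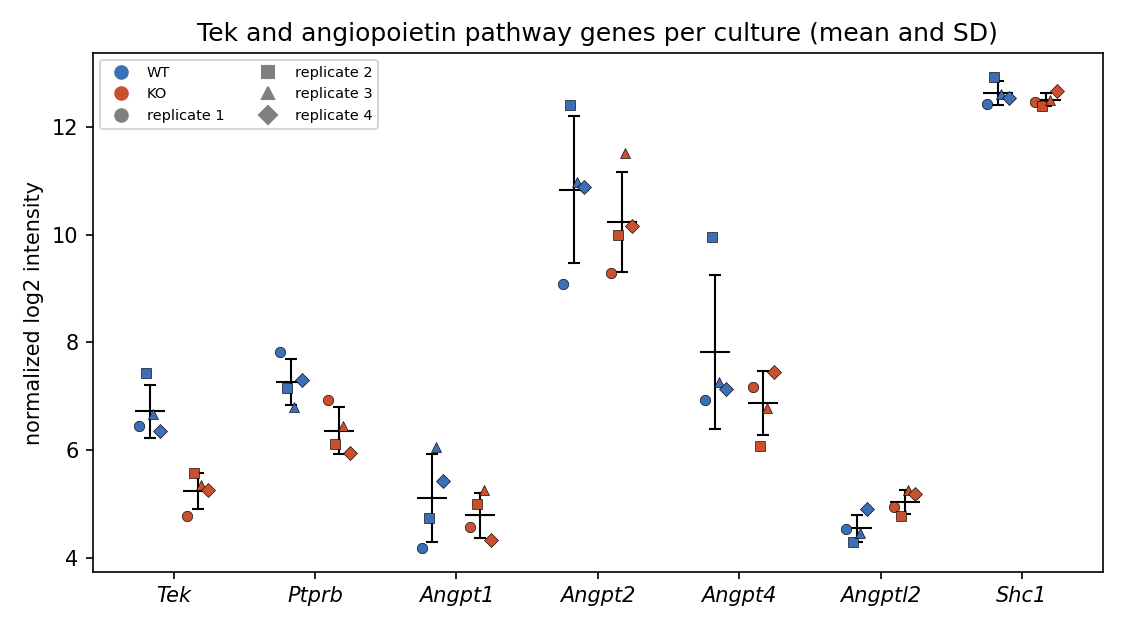
Normalized log2 intensity of 7 genes in each culture, with WT in blue, KO in red, a marker shape for each replicate number, and the mean with SD of 4 cultures in black. Tek in the 4 KO cultures lay between 4.78 and 5.56, below the 4 WT cultures at 6.35 to 7.42, while the groups overlapped for the other genes shown.

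Of the other angiopoietin and Tie genes, 0 passed the threshold, either over all genes or adjusted over the list alone. Ptprb, a receptor phosphatase that acts on Tie2, had a log2 fold change of -0.90 with a standard error of 0.28, and its limma p adjusted over the list alone was 0.069. The ligand genes Angpt1, Angpt2 and Angpt4 had log2 fold changes of -0.31, -0.59 and -0.96 with standard errors of 0.40, 0.70 and 0.66. When 1 culture was left out they ranged from -0.62 to 0.01, from -1.18 to -0.07 and from -1.26 to -0.25, and the values nearest 0 for Angpt2 and Angpt4 were those without WT replicate 2. Angptl2, an angiopoietin-like gene, stood at +0.50 with a standard error of 0.19. Its probe was detected on 1 of 4 WT and 3 of 4 KO arrays, and its log2 fold change was 0.16 in the authors' value table. The log2 fold changes of Dok2, Grb14, Shc1 and Angptl4 were -0.63, -0.14, -0.12 and -0.12, and those of Tnip2, Svep1 and Angptl1 were 0.04, 0.03 and 0.25. Leaving out 1 culture moved Dok2 between -1.22 and -0.06 and Shc1 between -0.19 and -0.02, and turned the sign of the other 5. 9 of the 13 genes, Tek included, were lower in KO by sign. The list had a camera adjusted p of 0.21, an adjusted p of 0.90 with an estimated correlation and an exact permutation p of 0.057 for its score. The score difference was -0.34, and -0.21 without WT replicate 2. These list values all include Tek, so they do not show a shift of the pathway beyond Tek. Dok2, Angptl1, Angptl4, Tnip2 and Svep1 changed sign within slide 1.

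Across the 11859 genes, 0 passed an adjusted p of 0.05 in limma and 0 passed 0.1. The smallest adjusted p was 0.16. 681 genes (5.74%) had an unadjusted p under 0.05, 310 of them higher and 371 lower in KO. The groups did not overlap for 389 genes (3.28%), against 2.86% given by chance for 4 arrays against 4, and 191 of these were higher and 198 lower in KO. Means differed by at least 2-fold for 205 genes. The median SD of a gene within a group was 0.31 in WT and 0.33 in KO. Of the 2894 tested probes without a gene, 0 passed and 249 had an unadjusted p under 0.05.

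The genes lower in KO with the smallest p included, besides Tek, a collagen, an integrin and a semaphorin receptor, and none passed the threshold. Col13a1, a transmembrane collagen, was detected on all 4 WT arrays at 5.48 ± 0.15 (SD, n = 4) and on 0 of 4 KO arrays at 4.26 ± 0.07 (SD, n = 4), at least 1.90-fold lower in KO. Its limma adjusted p of 0.16 was the smallest of all genes. This bound and those of the other genes hold for the neqc background alone, and the log2 fold change of Col13a1 was -0.45 in the authors' value table, -0.46 without background correction, -0.63 with normexp at an offset of 50 and -0.04 with the control-like probes as negative controls. Car14, a carbonic anhydrase, had a log2 fold change of -1.02 with a standard error of 0.19. Plxna4, the semaphorin receptor plexin A4, stood at -0.96 with a standard error of 0.18, and Itga6, the laminin receptor integrin α6, at -0.84 with a standard error of 0.17. Mdm4, a regulator of p53, stood at -0.93, Pla2g3, a secreted phospholipase, at -0.68, and Ncoa2, a nuclear receptor coactivator, was at least 1.71-fold lower through a probe detected on 0 of 4 KO arrays. The probes of Mdm4, Car14 and Pla2g3 were detected on 1, 2 and 2 of 4 KO arrays. A second probe gave 0.17 for Plxna4, 0.10 for Itga6 and 0.15 for Ncoa2, so that for these 3 genes the probes disagreed in sign. The second probe was detected on 3 of 4 arrays of each group for Plxna4, and on 2 of 4 for Itga6 and Ncoa2. These second probes lay between 4.195 and 5.66, near background, so the disagreement weighs little. DXBay18, detected on 0 of 4 KO arrays, was at least 2.07-fold lower, and the remaining gene of the 10 was a predicted locus.

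The genes higher in KO with the smallest p did not pass either. Ctbp2, a transcriptional corepressor, stood at 7.26 ± 0.09 (SD, n = 4) in WT and 8.00 ± 0.11 (SD, n = 4) in KO, a log2 fold change of 0.73 with a standard error of 0.13. Vasp, an actin regulator, had a log2 fold change of 1.05 with a standard error of 0.22. Zfp606, a zinc finger gene, stood at 0.90 and Tmprss11a, a transmembrane serine protease, at 0.68. The probes of 4 named genes were detected on 0 of 4 WT arrays and on all 4 KO arrays. They were those of Egf, the epidermal growth factor (at least 1.73-fold higher), Ifne, an interferon (at least 1.71-fold), Ripply3, a transcriptional repressor (at least 1.57-fold), and Saa1, an acute phase protein (at least 1.55-fold). In the authors' value table the log2 fold changes of these 4 genes were 0.28, 0.30, 0.26 and 0.30, and that of Vasp 0.43. A second probe gave 0.18 for Ctbp2, 0.10 for Zfp606 and -0.43 for Egf, where it was detected on 3 of 4 WT arrays. The other 2 genes of the 10 were unnamed loci. The limma adjusted p of the 10 genes was 0.81 or 0.83.

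**Figure D2:**
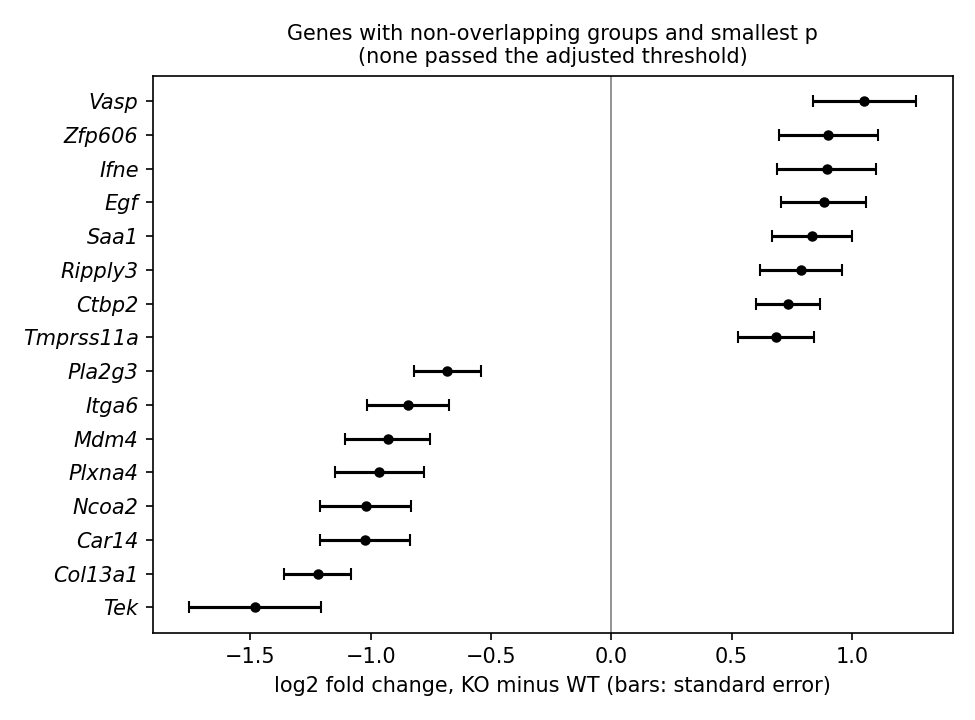
Log2 fold change, KO minus WT, of genes with non-overlapping groups and the smallest p, without DXBay18 and the unnamed loci, with bars for the standard error of the limma fit over 4 WT and 4 KO arrays. None passed the adjusted threshold, and for Col13a1, Ncoa2, Egf, Ifne, Ripply3 and Saa1, whose plotted probes were undetected in 1 group, the plotted value is the fitted one and not a bound.

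Of the 39 gene lists, 3 passed camera at a preset correlation, and 0 passed with an estimated correlation or with fry. The contractile smooth muscle list was higher in KO, with 25 of 25 tested genes higher by sign, a median log2 fold change of 0.51 and a camera adjusted p of 1.3e-06. The adjusted p was 0.90 with an estimated correlation. 0 of its genes passed over all genes and 0 adjusted over the list alone. Mustn1, a muscle nuclear protein, had a log2 fold change of 1.58 with a standard error of 0.53, and Csrp1, a cytoskeletal LIM protein, 0.73 with a standard error of 0.25. Myl9, the myosin regulatory light chain, stood at 0.80 and the integrin subunit gene Itga8 at 0.83. Myh11, Lmod1 and Tagln, chosen after their values were seen, stood at 1.18, 1.12 and 0.80, with standard errors of 0.58, 0.57 and 0.41. Without WT replicate 2 they were 0.53, 0.48 and 0.40, and Myl9 was 0.47. The brightest probe of Acta2, smooth muscle actin, also chosen after its values were seen, lay near the top of the scale. It stood between 14.56 and 14.64 on all arrays, where a difference cannot be read. The other Acta2 probes gave 0.55, 0.44, 0.52 and, for the dimmest, 0.94. In WT replicate 2 these probes stood at 12.833, 13.055, 12.91 and 5.118, each the lowest of the 8 cultures. In the other cultures all of these probes but the dimmest lay between 14.075 and 14.618, also near the top of the scale. Their differences therefore rested largely on WT replicate 2. The score of the contractile list was -0.04, -1.05, -0.30 and 0.28 in WT replicates 1 to 4 and 0.40, 0.12, 0.41 and 0.19 in KO replicates 1 to 4. The score difference was 0.56, and the exact permutation p was 0.086. It was 0.54 both with slide as a block and within slide 1, where the exact permutation p over 15 assignments was 0.33. Without WT replicate 2, the lowest culture, it was 0.30.

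The positional Hox list, whose genes record the place of a cell along the body axis, was higher in KO in 17 of 19 genes by sign, with a median log2 fold change of 0.44 and a camera adjusted p of 0.0050. The adjusted p was 0.90 with an estimated correlation, and the exact permutation p of the score was 0.086. 0 genes passed over all genes and 0 adjusted over the list alone. Hoxd4, Hoxb9, Hoxb6 and Hoxa5 had log2 fold changes of 0.87, 0.77, 0.68 and 0.29, with standard errors of 0.33, 0.40, 0.38 and 0.19. Hoxb6 and Hoxa5 stood at 0.41 and 0.17 without WT replicate 2, and without KO replicate 1 Hoxb9 stood at 1.16. WT replicate 1 had a score of -1.12, against -0.13 to 0.28 in the other WT cultures and 0.06 to 0.37 in KO. In that culture Hoxc9, chosen after its values were seen, was 5.26, against 10.04 or more in each of the others. The score difference of 0.50 was 0.40 with slide as a block and within slide 1. Without WT replicate 1 it was 0.21 and the camera adjusted p 0.14, in a range of 0.00027 to 0.95 over the alternatives.

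**Figure D3:**
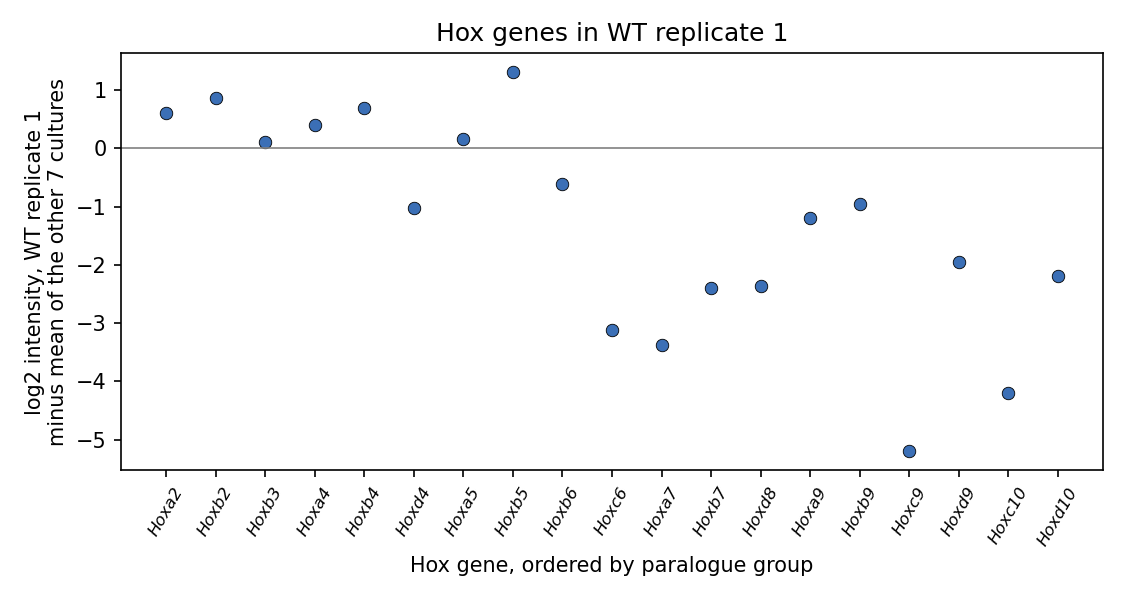
Log2 intensity of the 19 tested Hox genes in WT replicate 1 minus the mean of the other 7 cultures, ordered by paralogue group from anterior to posterior. Each point is 1 gene, and the values run from 1.31 for Hoxb5 to -5.20 for Hoxc9.

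**Figure D4:**
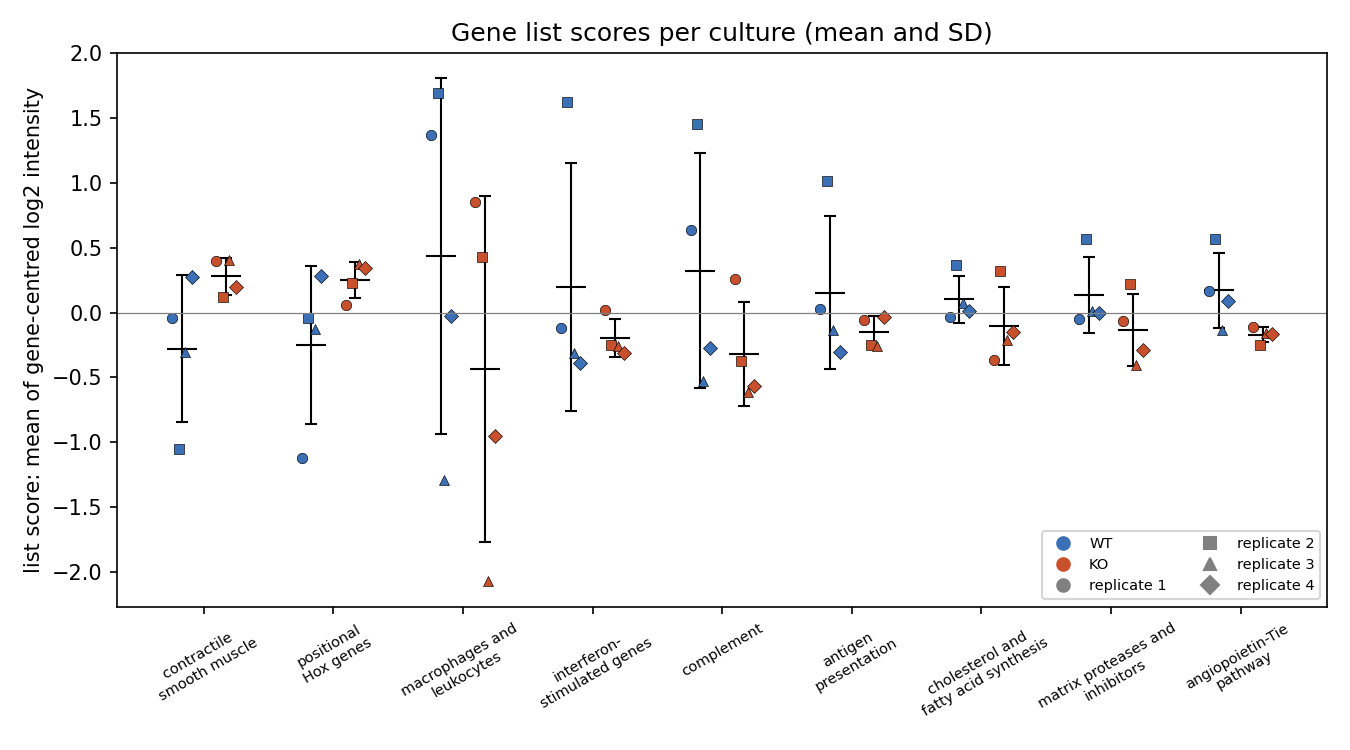
Scores of the 9 described gene lists in each culture, as the mean of gene-centred log2 intensities, with WT in blue, KO in red, a marker shape for each replicate number, and the mean with SD of 4 cultures in black. The lowest contractile score was -1.05 in WT replicate 2, the lowest Hox score was -1.12 in WT replicate 1, and the macrophage and leukocyte scores ran from -2.08 to 1.69.

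The list of macrophage and leukocyte markers was lower in KO in 20 of 21 genes by sign, with a median log2 fold change of -0.89 and a camera adjusted p of 0.0050. The adjusted p was 0.90 with an estimated correlation, and the exact permutation p of the score was 0.37. 0 genes passed over all genes and 0 adjusted over the list alone. C1qa, a subunit of complement C1q made by macrophages, had a log2 fold change of -1.79 with a standard error of 1.01, and Cd52, a leukocyte surface protein, -1.57 with a standard error of 1.18. C1qa stood at -1.10 without KO replicate 3, and Cd52 ranged from -2.43 without WT replicate 3 to -0.87 without KO replicate 3. The class II antigen presentation genes H2-Aa and H2-Ab1 stood at -0.89 and -0.98, and the second probe of H2-Ab1 at 0.03. Scores were 1.37, 1.69, -1.29 and -0.03 in WT replicates 1 to 4 and 0.86, 0.43, -2.08 and -0.96 in KO replicates 1 to 4. The score difference of -0.87 became 0.21 with slide as a block and within slide 1, where the camera adjusted p was 0.57 in the opposite direction. The KO cultures of slide 1, replicates 1 and 2, nonetheless each scored below the WT culture of the same number, though the labels do not pair them. The difference was -0.56 without WT replicate 1, -0.45 without WT replicate 2, -1.45 without WT replicate 3 and -0.33 without KO replicate 3. Without WT replicate 1, WT replicate 2, KO replicate 3 or KO replicate 4 the camera adjusted p was 0.20, 0.32, 0.37 or 0.060, in a range of 9.7e-15 to 0.96 over the alternatives.

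The remaining described lists were lower in KO by sign and did not pass, each with an adjusted p of 0.90 with an estimated correlation and 0 genes past the threshold over all genes or adjusted over the list alone. The interferon-stimulated list was lower in 22 of 26 genes, with a camera adjusted p of 0.11 and a median log2 fold change of -0.34. Zbp1, Trim30a, Psmb9 and Usp18, genes induced by interferon, had log2 fold changes of -0.59, -1.26, -0.84 and -0.92 with standard errors of 0.32, 0.81, 0.65 and 0.72, and of -0.35, -0.47, -0.12 and -0.10 without WT replicate 2. Trim30a stood at -0.74 without KO replicate 4. The score of the list was 1.62 in WT replicate 2 and between -0.39 and 0.02 in the others, and the difference of -0.40 was 0.08 without that culture. The complement, antigen presentation, cholesterol and fatty acid synthesis, and matrix protease lists each had a camera adjusted p of 0.11. The complement list was lower in 12 of 14 genes, with a median of -0.67. Its score difference of -0.64 was -0.27 without WT replicate 2 and 0.08 without WT replicates 1 and 2. Cfi, complement factor I, stood at -1.45 with a standard error of 0.64, C4a at -1.10, and Cd55, a complement inhibitor on the cell surface, at 0.51, and without WT replicate 2 these were -0.90, -0.48 and 0.30. Cd55 stood at 0.84 without WT replicate 1. The antigen presentation list was lower in 12 of 14 genes, with a median of -0.27. Psmb10, an immunoproteasome subunit, stood at -0.47 with a standard error of 0.21 and did not overlap between the groups, and the class I genes H2-Q7 and H2-K1 at -0.74 and -0.64, where second probes gave 0.48 and 0.01. That of H2-Q7 was detected on 1 of 4 WT and 3 of 4 KO arrays. Through their brightest probes H2-Q7 and H2-K1 stood at -0.40 and -0.21 without WT replicate 2, and H2-K1 at -0.42 without KO replicate 3 or KO replicate 4. The score of this list without WT replicate 2 differed by -0.02, against -0.30 with all cultures.

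The cholesterol and fatty acid synthesis list was lower in 16 of 20 genes, with a median of -0.17. Its score difference of -0.21 was -0.12 without WT replicate 2 or KO replicate 1 and -0.35 without KO replicate 2. Idi1 and Mvd, enzymes of the mevalonate pathway, stood at -0.97 and -0.43, and the desaturases Scd1 and Scd2 at -0.43 and -0.62. Mvd and Scd1 stood at -0.20 and -0.22 without WT replicate 2, Mvd at -0.21 without KO replicate 1, and without KO replicate 4 Scd2 stood at -0.40. The list of matrix proteases and their inhibitors was lower in 19 of 25 genes, with a median of -0.24. Its score difference of -0.27 was -0.12 without WT replicate 2 and -0.18 without KO replicate 3. Adamts1, Adam12, Adam17 and the cathepsin gene Ctsk had log2 fold changes of -0.60, -0.69, -0.46 and -0.60, with standard errors of 0.22, 0.27, 0.24 and 0.37. Adam17 and Ctsk stood at -0.24 and -0.31 without WT replicate 2, Ctsk at -0.91 without WT replicate 1, and without KO replicate 3 Adam12 stood at -0.46. Second probes of Adamts1, Adam12 and Adam17 gave 0.34, 0.23 and 0.15, that of Adam12 detected on 2 of 4 WT and 3 of 4 KO arrays. The score differences with slide as a block and within slide 1 were -0.32 for interferon-stimulated genes, -0.38 for complement, -0.31 for antigen presentation, -0.13 for cholesterol and fatty acid synthesis, -0.05 for matrix proteases and -0.35 for the angiopoietin and Tie list.

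Among markers of other cell types, endothelial genes were higher in KO in 11 of 18 by sign, with a median log2 fold change of 0.21 and a camera adjusted p of 0.72. Tek itself is in that list and was its 1 gene past the threshold adjusted over the list alone. The lists for adventitial fibroblasts and pericytes had medians of -0.10 and 0.12 and camera adjusted p-values of 0.78 and 0.75. The striated muscle list had a camera adjusted p of 1.00. Its 1 gene past the threshold adjusted over the list alone was Myh7, a cardiac myosin chosen after its values were seen. Myh7 was detected on 0 of 4 KO arrays and was at least 1.51-fold lower there. Its limma p adjusted over the list alone was 0.014, and its limma adjusted p over all genes was 0.83. The log2 fold change of Myh7 was -0.87, against -0.40 in the authors' value table and -0.04 in the alternative nearest 0. The cell cycle list had 15 of 33 genes higher in KO and a median of -0.02, and the fibrillar collagen list 12 of 22 and a median of 0.06, neither past camera, with adjusted p-values of 0.99 and 0.75. The mean of the collagen list was -0.11, opposite in sign to its median. With slide as a block and within slide 1 the score differences were -0.03 for endothelial cells, -0.11 for adventitial fibroblasts, -0.09 for pericytes, 0.45 for striated muscle, 0.24 for cell cycle and -0.14 for fibrillar collagens. The 30 lists outside the plot of list scores had camera adjusted p-values between 0.36 and 1.00.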

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

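Among the tests below, the splits of the arrays for gene lists and for the contractile list were set before their results were seen, and the other tests were chosen after the results they bear on were seen. A value is given here where 1 culture lay far from the other 3 of its group. 29 of 246 groups of 4 values met this, where chance gives about 1 in 20, or 12.3. Leaving out genes chosen after their values were seen, 19 of 202 groups met it, against 10.1 by chance, and 8 of the 19 were in WT replicate 2.

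In WT replicate 2 the interferon-stimulated genes Isg15, Oasl2 and Usp18 were high at log2 intensities of 11.52, 10.81 and 10.06, and the interferon-stimulated list score was 1.62. In the same culture the class I gene H2-K1 was 10.59, Angpt4 9.96, Mvd 8.64 and Tmprss11a 4.93, all high, and the matrix protease score was 0.57, also high. Myh11 was low there at 5.23 and the cell cycle score at -0.37. In WT replicate 1, Hoxc9, Hoxc10, Hoxc6, Hoxa7 and Hoxb7 were low at 5.26, 4.53, 8.57, 5.45 and 8.48, and a predicted locus was high at 5.92. In WT replicate 3, Saa1 was high at 4.71. In KO replicate 1, Hoxb9, Hoxa5 and Hoxa7 were low at 4.28, 10.57 and 7.67, H2-Aa was high at 5.17, and the scores of the interferon-stimulated and NRF2 lists were high at 0.018 and 0.69. In KO replicate 2, Egf, Pla2g3 and Angptl1 were low at 4.91, 4.49 and 4.61 and Myh7 was high at 4.91. In KO replicate 3, Adam17 was low at 8.47. Saa1 was detected on 0 of 4 WT arrays, Tmprss11a on 1 of 4 WT arrays, Myh7 on 0 of 4 KO arrays and H2-Aa on 1 of 4 KO arrays. Their flagged values therefore lay near background.

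The arrays can be split into 4 and 4 in 35 ways, the real one included. The real split called 0 genes, the lowest count there is, so that 35 of 35 splits had to give as many and the count says nothing about chance, and the highest other split called 1. For unadjusted p under 0.05 the real split had 681 genes, and 13 of the 35 splits had as many, up to 1630. The real split put 3 lists past camera, and 32 of 35 splits put at least 3 past it, with up to 17 in another split. Chance is therefore not excluded for the number of lists. A structure among the cultures could give splits with many lists, and so could the preset correlation of 0.01, which lies below the estimated 0.51 of the contractile list, 0.67 of the macrophage list and 0.55 of the interferon-stimulated list, and no test separated them.

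The contractile list stood higher in KO, with WT replicate 2 lowest. 4 of the 35 splits gave the list a camera p as small as the real 3.4e-08, the smallest other being 6.1e-14, so chance is not excluded here either. Without WT replicate 2 the score difference was 0.30 with a standard error of 0.18, against 0.56 with all cultures, which does not settle whether that culture alone makes the difference. Fewer cells in KO that lack both contractile and fibrillar collagen genes, such as macrophages, would raise both alike. The difference between the groups in contractile minus collagen score was 0.67, with a standard error of 0.34 and an exact permutation p of 0.086, which leaves this open. The comparison cannot address fewer cells of a type that itself makes collagen. Tek deletion itself, the biological difference the design names, stays open and untested beyond these values. It cannot be told apart from an effect of the Cre transgene, since no culture carried Cre without the floxed gene.

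Posterior Hox genes were low in WT replicate 1. That array was the dimmest, with a median intensity of 94.7 against 108.9 to 128.1, though it detected 48.0% of probes, within the 44.9% to 49.5% of the others. Its weaker signal as the whole cause is argued against, since before normalization 10 of the 11 tested genes of paralogue groups 6 to 10 lay below the lowest 5% of genes of like brightness, with a median of -1.99 from the other cultures against -0.44. A candidate explanation is another stretch of the aorta, as after normalization these 11 genes lay a median of -2.37 from the mean of the other cultures, and the 8 genes of groups 1 to 5 a median of 0.51 above it, with Hoxd4 at -1.03. No label gives the stretch of aorta, and with the control-like probes as negative controls the posterior median was -0.49.

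Macrophage and leukocyte markers spread widely between cultures within both groups. The slide as the whole cause is argued against, since the score ranged over 2.98 log2 units within slide 1, of 3.77 over all cultures. Macrophages carried over from the vessel wall in differing amounts are a candidate explanation. 19 of the 21 tested markers correlated at over 0.5 with the mean of the other markers, the exceptions being Cd3e and H2-Ab1. This correlation does not show which cells held the transcripts. The brightest markers Lyz1, Lyz2 and Laptm5 stood at log2 intensities of 12.09, 10.55 and 10.68 even in their lowest cultures. Their highest values were 14.59, 13.95 and 13.41. They ranged over 2.50, 3.40 and 2.73 log2 units between cultures, and Fcer1g and C1qb over 5.34 and 5.19. Of the 21 markers, 4 also stand in the complement or protease lists. Genotype stays open, with a difference of -0.87, a standard error of 0.96 and an exact permutation p of 0.37. Both the standard error and this p take the cultures as unpaired. In both groups replicates 1 and 2 scored higher than replicates 3 and 4, and this shared spread enters the standard error. What same-numbered cultures had in common is not given by the labels and was not tested. In each same-numbered pair the KO culture had the lower score, though the labels do not say that the numbers pair the samples.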

How the results depend on the processing

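The control-like probes as negative controls and the fit without both outlying WT cultures were chosen after seeing the data. In the count of genes differing between KO and WT, limma gave 0 under all alternatives run, and the genes at unadjusted p under 0.05 numbered 464 to 1188. Tek was lower in KO in all 24 alternatives that gave it a value and passed over all genes in none, with log2 fold changes of -1.60 to -1.25 when a culture was left out and of -0.09 at the smallest. Of the 68 other named genes 57 kept their direction and 0 passed. In 36 of all 69 named genes leaving out 1 culture moved the log2 fold change by over 1.5 times, in 30 of them when it was WT replicate 2. 19 differences of 1 culture from the others kept their sign in 133 of 133 values under other backgrounds, scalings and probe rules, and 55 moved by over 1 SD. Signal over background limits dim genes. Of the 20 genes with non-overlapping groups and the smallest p, Tek included, 19 had a log2 fold change over 1.5 times smaller under each of 4 other backgrounds, the exception being Ctbp2. The median log2 fold change of all genes lay between -0.019 and 0.055 under the scalings and backgrounds compared.

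The number of lists past camera, 3, became 5 with median scaling, 1 with array quality weights, 0 with an estimated correlation, 0 with fry, 1 without both outlying WT cultures and 1 to 6 when a culture was left out (1 without WT replicate 1, 6 without WT replicate 3 or 4). The cause was not tested. The contractile list kept its side of the threshold except with an estimated correlation and fry. The Hox list lost it also with array weights (adjusted p 0.12), control-like negatives (0.056), without WT replicate 1 (0.14) and without both outlying WT cultures (0.16), of a range of 0.00027 to 0.95. The macrophage and leukocyte list lost it in 7 of 25 alternatives, array weights among them, and turned upward without passing in 3 others. The interferon list gained it in 8 of 25 alternatives, the complement list in 4, the antigen presentation and cholesterol lists in 2 each and the matrix protease list in 1. Camera takes no random block, so that fit gave no list values.

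The labels do not say whether the replicate numbers pair the samples, and they were not treated as pairs. Deviations of same-numbered cultures correlated at 0.32, 0.21, 0.29 and 0.063 across genes, not all over 0.1, though 8 of 8 samples correlated best with their own number. The replicate block gave 0 genes (1005 at unadjusted p under 0.05, against 681) and 8 lists past camera, the macrophage list with an adjusted p of 9.7e-15. Its score was lower in KO in 4 of 4 same-numbered pairs, which holds as a hint from the data and not from the design.

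Results that reversed were as follows, and the cause was not tested. With slide as a fixed block, and equally for slide 1 alone, the log2 fold changes were 0.53 for Dok2, -0.18 for Tnip2, -0.15 for Svep1, -0.44 for Angptl1, 0.77 for Angptl4, 0.023 for H2-K1 and 0.17 for Cd52, and the macrophage list turned upward with adjusted p-values of 0.54 and 0.57. Slide as a random block gave Angptl4 0.035, and array weights gave Grb14 0.038. Leaving out each culture gave ranges that crossed 0 of -0.62 to 0.0076 for Angpt1 (reversed without WT replicate 3), -0.35 to 0.071 for Grb14 (WT replicate 1), -0.13 to 0.19 for Tnip2 (WT replicate 4 and KO replicate 3), -0.27 to 0.22 for Svep1 (WT replicate 4, KO replicates 1 and 4), -0.24 to 1.06 for Angptl1 (WT replicates 2 and 3, KO replicate 3) and -0.53 to 0.38 for Angptl4 (KO replicate 3). The interferon list had adjusted p-values of 0.0019 to 0.47, and turned upward without WT replicate 2. Control-like negatives gave Angptl1 -0.046 and Angptl4 0.15. Without both outlying WT cultures Dok2 was 0.51, Grb14 0.28, Psmb9 0.15 and C4a 0.057, and 4 lists turned upward, the interferon list with an adjusted p of 0.12 and the antigen presentation, complement and macrophage lists with 0.59.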

Other observations

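The genes near Tek were tested by a test set before its result was seen, and the genes and scores below were chosen after their values were seen. Il33, an alarmin cytokine, had the largest log2 fold change of the genes detected on all 8 arrays. Its log2 intensity was 6.36, 11.08, 10.24 and 9.63 in WT replicates 1 to 4 and 6.47, 7.57, 5.48 and 7.05 in KO replicates 1 to 4. The log2 fold change was -2.68 with a standard error of 0.94 and an exact permutation p of 0.11, as WT replicate 1 lay among the KO cultures. Cck, the cholecystokinin gene, stood at 2.43 with a standard error of 1.04 and an exact permutation p of 0.11, and Il11, a cytokine of the IL-6 family, at 1.52 with a standard error of 0.54 and an exact permutation p of 0.057. Without WT replicate 2 Cck stood at 1.58 and Il11 at 0.97. The limma adjusted p of these 3 genes was 0.83.

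WT replicate 2 had the lowest score of the 8 cultures in several further lists, at -0.78 for the Notch list, -1.24 for striated muscle, -0.80 for the BMP list and -0.55 for smooth muscle transcription regulators. KO replicate 3 had the highest Schwann cell and neuron score at 1.26 and the lowest cell cycle score at -0.51.

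Of the 50 tested genes nearest to Tek in the order of assembly GRCm38.p6, 25 on each side, 3 had an unadjusted p under 0.05, or 6.0%, against 5.73% of the other tested genes (Fisher's exact p = 0.76). Both groups carried the floxed gene per the labels, so this comparison says nothing about sequence carried along with the floxed allele.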
